A study of Arabidopsis thaliana with 6 samples.

How the data were processed

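RNA of 6 samples of fluorescence-sorted Arabidopsis thaliana root cells was hybridised to Affymetrix ATH1 arrays, 1 array per sample. The cells came from seedlings of the C24 ecotype grown for 5 days, and biotin was introduced by 2 rounds of labelling, per the labels. There were 3 groups of 2 biological replicates: untreated, 1 h of dexamethasone and 4 h of dexamethasone. No group lacked the inducible construct, so an effect of dexamethasone itself, of the sort, or of the hours that passed cannot be separated from an effect of the induced protein.

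The deposited table holds 1 intensity value per probe set and array on a linear scale. The labels and the table do not name the software that summarised the probes. In every column the mean after trimming 2% at each end was 250.03 at 5 significant digits, so the columns had been scaled to a common level before deposit. The table has 22810 rows, of which 64 are control probe sets. The 22746 others were tested.

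From there, log2 of the value plus a pseudocount of 16 was taken. Column medians on that scale spanned 0.215, more than the 0.1 set as the limit for leaving the columns alone, and the columns were therefore quantile normalized. A linear model with a mean per group was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, and its moderated test was applied to 3 contrasts: 1 h against untreated, 4 h against untreated, and 4 h against 1 h. P-values were adjusted over the 22746 probe sets of a contrast by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a change. All p-values are two-sided and measure differences against the spread between arrays, pooled over the 3 groups. Standard errors (SE) are those of this fit, on the log2 scale, and n is 2 arrays per group unless stated otherwise.

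Genes were named through the platform annotation of 2016 and a RefSeq gene table of assembly TAIR10.1. Of the probe sets, 13513 carry 1 gene in that annotation, 503 carry several and 8730 are not listed; 13436 of the first kind were matched to a locus. Probe sets without a single gene are given by their identifier. A gene with several probe sets (147 genes) is represented by the one with the highest mean. Under this annotation ARR1, PIN5, GH3.6 and IAA3 have no named probe set, so their levels were not analysed here, and the level of the ARR1 fusion cannot serve as a check of the labels. The array was designed on another ecotype than C24.

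The rule for naming genes had 3 parts. GH3.5 and GH3.17, with the genes just listed, were to be given in every contrast. The 8 largest rises and falls past the threshold whose groups did not overlap followed, filled up to 5 genes per direction with those of the smallest unadjusted p, described as not passing. From each gene list up to 3 members past the threshold were named, or the 2 members with the largest difference where none passed. The 23 lists hold 323 entries on cytokinin response, auxin, cell types of the root, cell wall, hormones, stress, clock, photosynthesis and reference genes. Only 50 entries could be measured under the annotation, and 1 more was left out because its symbol did not match its locus. Of the lists, 6 had no measured member, 10 had 1 or 2 and are given by their members, and 7 with at least 3 were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 21 tests. The lists, the tests of the 3 contrasts and of the lists, and the alternatives were fixed before the data were examined, except a filter on background, array weights and the families of genes that share a symbol or an organelle genome, which were added after. Genes were assigned to the plastid or mitochondrial genome by the first letters of their symbol, not by locus, so either set may hold misassigned genes.

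As a measure of background, chosen after seeing the data, the 95th percentile of the 27 Bacillus subtilis control probe sets was taken on each array. Where a gene lay below it on both arrays of 1 group, the difference is given as a bound ("at least"), computed against the lowest normalized level that exceeded background on each array of that group. No fold is given where the bound came to less than 1 or both groups lay below background. The bound uses the mean of the brighter group without its spread, so it is not a confidence limit. It is weakest where only 1 array of that group exceeded background.

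The fit was tested on simulated arrays with the real levels and spread of the 22746 probe sets, 200 of them changed in 1 group. At 8-fold, 76.5% were recovered for 1 h against untreated, 85.0% for 4 h against untreated and 81.5% for 4 h against 1 h. At 4-fold the shares were 29.5%, 0% and 0%, and at 2-fold 0% in each. Each share came from 1 simulated set, and the contrasts were simulated alike apart from the random draw. Differences between the contrasts in these shares therefore do not show that 1 contrast has more power than another. With a prior variance that follows the signal level, a further setting fixed in advance, the shares at 4-fold were 54.5%, 49.0% and 48.5%, with at most 8 false calls in any of these simulations. The simulated spread was itself drawn from that level-dependent fit, with independent probe sets and equally variable arrays. The comparison therefore favours that fit, and its false calls on the real arrays were not measured. The number of arrays limits the precision of all values. Figures were drawn with matplotlib 3.10.9. Alternatives covered the scaling, the pseudocount, filters on dim probe sets, the prior variance, the arrays and thresholds used, the replicate number as a block and each array left out.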

Results

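Transcript levels were measured in lateral root cap cells, the outer cell layer that sheathes the growing root tip, sorted by the fluorescence of the J2632 enhancer trap line. In these plants the same line drives a fusion of ARR1, a transcription factor of the cytokinin response, with the glucocorticoid receptor. The ARR1 part lacks the domain that restrains it, and the receptor part keeps the protein out of the nucleus until dexamethasone is added. The 6 arrays covered untreated seedlings and seedlings after 1 h and 4 h of dexamethasone, with 2 biological replicates each. Between 58.1% and 67.8% of the 22746 probe sets exceeded the background on an array.

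The 4 h arrays stood apart from the rest. The correlation of log2 signals within a group was 0.957 for the untreated pair, 0.958 for the 1 h pair and 0.972 for the 4 h pair. Between groups it ranged from 0.953 to 0.969. Untreated replicate 2 correlated more with each of the 4 dexamethasone arrays (0.958 to 0.969) than with the other untreated array (0.957). Only the 4 h pair was thus more alike than all arrays of different groups. The first principal component held 27.3% of the variance, with the 4 h arrays at 35.7 and 44.3 and the other arrays between -32.2 and -11.0. The second held 23.7% and set untreated replicate 1, at -57.6, against all other arrays (-0.84 to 26.2). The third held 21.1% and set 1 h replicate 1, at 55.5, against all others (-18.2 to 0.05). The control ratio of 3' to 5' signal for GAPDH, a sign of RNA quality, ranged from 3.11 to 4.65, with 3.11 on untreated replicate 1 and 4.65 on 1 h replicate 1. Transcripts of the plastid genome also differed between arrays: the median of 69 genes, relative to each gene's mean, was -0.42 and -0.25 at 4 h, -0.31 and 0.40 in the untreated replicates, and 0.04 and 0.52 at 1 h. On the same arrays the 25S ribosomal RNA control read 6422 and 6680 at 4 h, 8221 and 9688 untreated, and 7668 and 10831 at 1 h.

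**Figure D1:**
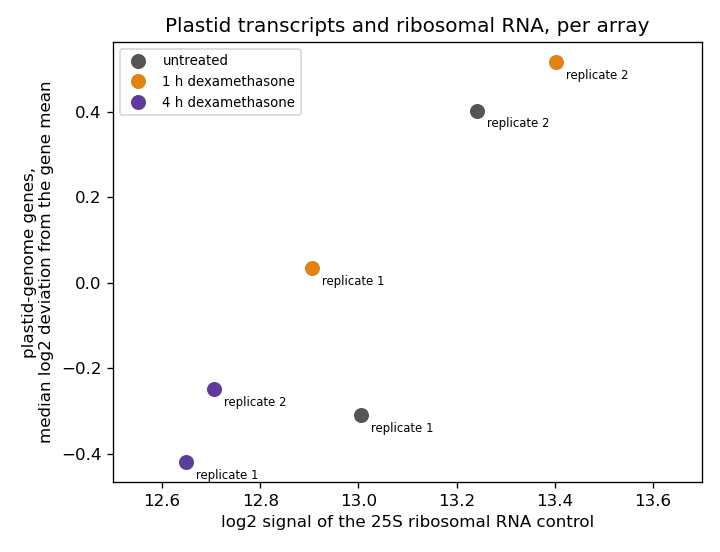
Median log2 deviation of 69 plastid-genome genes from each gene's mean (y axis) against the log2 signal of the 25S ribosomal RNA control (x axis), 1 point per array, coloured by group. The 4 h arrays have the lowest ribosomal RNA signals, and the highest values of both belong to 1 h replicate 2.

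The first comparison asked which genes respond within 1 h of ARR1 activation. No named gene passed the test, and the fast targets expected of a cytokinin response regulator could be followed only in part. RR16, a type-A response regulator of the kind that cytokinin induces, measured 4.77 ± 0.41 (SD, n = 2) on the log2 scale in untreated cells and 5.75 ± 0.35 at 1 h, with only 1 of these 4 arrays above background. Both untreated arrays lay below it, and the bound for RR16 was 1.07-fold in favour of 1 h. ARR15, of the same class, exceeded background on 1 of these 4 arrays, so no difference is given. Of the root cap genes the polygalacturonase AT1G65570 differed most: its log2 level was 9.47 ± 0.19 untreated and 10.61 ± 0.02 at 1 h, a log2 difference of 1.15 (SE 0.26, adjusted p = 0.759). Adjusted over the list alone, its p was 0.0138, the only one of the 4 root cap genes under 0.05. GH3.17 and GH3.5 (WES1 in the annotation), which couple auxin to amino acids, differed from untreated by -0.03 (SE 0.23) and 0.05 (SE 0.24).

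In the limma fit 0 of the 22746 probe sets passed at 1 h, with a smallest adjusted p of 0.759. At an unadjusted p under 0.05 there were 1314, against 1137 expected by chance; 671 were higher and 643 lower at 1 h. Most of the named genes with the smallest p were near background. AT1G19900 was below it in untreated cells and at least 2.98-fold higher at 1 h, and the lipase-like DLAH at least 1.82-fold. The bounds for AT3G58060 and AT1G72540, each above background on 1 array at 1 h, were 1.16-fold and 1.13-fold. In the other direction AT2G39280 was at least 1.38-fold higher in untreated cells, and the bound for AT1G32580 was 1.00-fold. AT1G12030 and AT4G01390 reached background only in untreated cells, and AT1G31530 and AT5G63180 on no array of either group. All 10 had an adjusted p of 0.759.

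None of the 7 lists tested passed at 1 h. The smallest adjusted p of camera was 0.164, for the root cap markers, whose 4 members were all higher at 1 h by a median of 0.22, with 0.23 (SE 0.24) for scpl48. The auxin biosynthesis genes had an adjusted p of 0.204, but of the 3 members only YUC2 exceeded background on every array of both groups, with a difference of 0.25 (SE 0.39). YUC6, a flavin monooxygenase of that pathway, exceeded background on 1 array at 1 h, and YUC4 on none of either group. The cell wall loosening genes were split: XTH18 differed by 0.78 (SE 0.26) and EXPA4 by -0.84 (SE 0.30), and the list of 4 had a median of 0.51 and an adjusted p of 0.455. For 7 Aux/IAA genes, repressors of auxin response, the adjusted p was 0.455, with 4 members above background on 2 or more of the 6 arrays; IAA30 differed by 0.88 (SE 0.36), and IAA34 lay below background. The 9 genes of auxin conjugation and inactivation had a median of 0.05 (adjusted p = 0.903), with 0.62 (SE 0.37) for GH3.1 and both groups below background for UGT84B1. The 5 early cytokinin-response genes, all of the glutaredoxin kind and among them AT4G15660, AT4G15690 and AT4G15700, were not detected: none exceeded background on more than 1 of the 6 arrays, so their list test (camera adjusted p = 0.489, 0.965 and 0.511 in the 3 contrasts) does not measure a response. The 3 reference genes had a median of -0.07 (adjusted p = 0.965), with 0.21 (SE 0.23) for AT4G34270 and -0.07 (SE 0.22) for AT2G28390.

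The 10 lists with 1 or 2 measured members gave no call over all probe sets at 1 h. The cyclin-dependent kinase inhibitor SIM differed by -0.07 (SE 0.25) and PRL by -0.03 (SE 0.37), the clock gene GI by 0.18 (SE 0.24), the stress-response zinc finger gene STZ by 0.15 (SE 0.22) and RCA, the Rubisco activase, by -0.08 (SE 0.29). UGT76C2, a cytokinin glucosyltransferase, differed by -0.35 (SE 0.35), while UGT76C1, the type-B regulator RR18, the quiescent centre marker AGL42, the root hair gene EXPA7 and the cortex marker AT1G62500 were below background in both groups. EXPA18 differed by 0.03 (SE 0.64), with 1 of 2 arrays above background in each group. For GSO1, a receptor kinase of the endodermal barrier, the bound was 1.07-fold in favour of untreated cells, where 1 of 2 arrays exceeded background. STZ, at 13.33 untreated and 13.48 at 1 h, was among the strongest signals of any listed gene.

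After 4 h, 1 probe set had changed, and by a large factor. The unnamed probe set 253534_at fell 25.7-fold, from a log2 level of 11.00 ± 0.01 (SD, n = 2) in untreated cells to 6.32 ± 0.41 (log2 difference -4.69, SE 0.26, adjusted p = 0.0227 in limma). YLS5, first described as a gene of leaf senescence, went from 12.10 ± 0.07 to 9.58 ± 0.15, a difference of -2.52 (SE 0.22) that missed the threshold at an adjusted p of 0.0816. AT2G22760 measured 6.25 ± 0.26 and 8.81 ± 0.14, a difference of 2.56 (SE 0.24, adjusted p = 0.0816). The wall-loosening genes XTH18 and XTH19, xyloglucan-modifying enzymes, and the expansins EXPA4 and EXPA15 were all higher at 4 h, by a median of 0.62, and were the only list to pass (camera adjusted p = 0.0161, but adjusted p = 0.607 with an estimated correlation). In the wider families, defined after seeing the annotation, 5 of 9 XTH genes were higher (median 0.06, camera adjusted p = 0.759) and 7 of 10 EXPA genes (median 0.29, adjusted p = 0.400). Plastid-genome transcripts lay at medians of -0.42 and -0.25 on the 4 h arrays, with untreated replicate 1 at -0.31 and untreated replicate 2 at 0.40.

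253534_at was the only probe set that passed against untreated; 2066 had an unadjusted p under 0.05, 1117 of them higher and 949 lower at 4 h, against 1137 by chance. Leaving out any 1 of the 6 arrays left 0, although its difference stayed between -4.98 and -4.39, and a fit with a prior variance that follows the signal level gave 123. Of the other named genes none passed. AT2G42270 differed by 2.17 (SE 0.28), AT3G02555 by 1.95 (SE 0.26) and AT2G43890 by -2.52 (SE 0.34), each with an adjusted p of 0.235. AT1G15640, below background at 4 h, was at least 2.14-fold higher in untreated cells (adjusted p = 0.113). The corresponding bounds were 1.49-fold for AT5G10800 and 1.11-fold for AT3G05620. AT4G28150 and AT1G62760, below background in untreated cells, were at least 1.92-fold and 1.39-fold higher at 4 h; these last 4 genes had an adjusted p of 0.235.

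Within the list of cell wall loosening, XTH18 went from 10.01 ± 0.22 to 11.02 ± 0.28 (log2 difference 1.00, SE 0.26), XTH19 differed by 0.63 (SE 0.24), and EXPA4 and EXPA15 each by 0.60 (SE 0.30 and 0.41). Over all probe sets none of the 4 passed, and adjusted over the list alone XTH18 did (limma adjusted p = 0.0312). Without untreated replicate 1, untreated replicate 2 or 4 h replicate 1 the list's adjusted p was 0.0947, 0.104 and 0.153, with medians of 0.69, 0.74 and 0.59.

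Genes that conjugate or oxidise auxin, the hormone whose level the lateral root cap is thought to tune, had a median of 0.53 at 4 h (9 genes, 6 of them higher, camera adjusted p = 0.304). GH3.17 was the clearest: 10.83 ± 0.15 untreated and 11.64 ± 0.00 at 4 h, a difference of 0.81 (SE 0.23, adjusted p = 0.390 over all probe sets and 0.0867 adjusted over the list alone). GH3.3 went the other way and was at least 1.38-fold higher in untreated cells, and GH3.5 (WES1) differed by -0.16 (SE 0.24). The count adjusted over the list alone was 0 of 9. Among the Aux/IAA genes the bound for IAA34, above background on 1 array at 4 h, was 1.08-fold in favour of 4 h. IAA29, with 1 of 2 arrays above background in each group, differed by 0.61 (SE 0.47). The Aux/IAA list had a median of 0.00 and a camera adjusted p of 0.711. Auxin biosynthesis (median 0.10, adjusted p = 0.677) included YUC2 at 0.10 (SE 0.39).

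**Figure D2:**
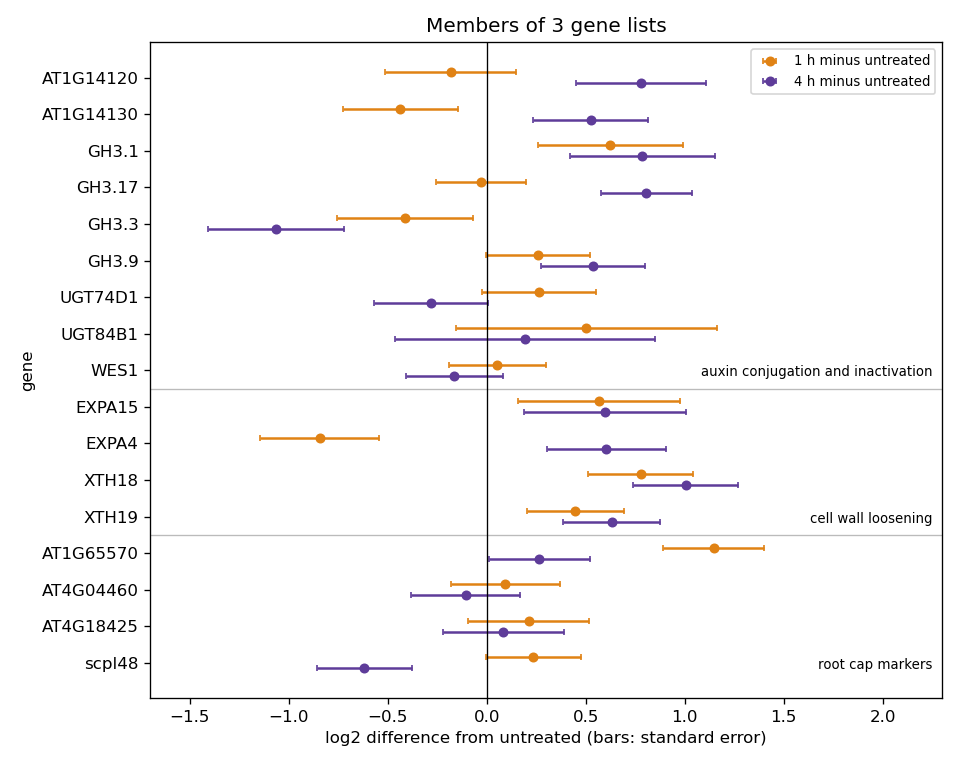
Log2 difference from untreated after 1 h and 4 h (x axis) for each measured member of 3 gene lists (y axis); points are differences of group means of 2 arrays and bars the standard error of the fit. All 4 wall-loosening genes lie above 0 at 4 h, and EXPA4 lies at -0.84 at 1 h.

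For the root cap markers the median at 4 h was -0.01 (camera adjusted p = 0.871), with -0.62 (SE 0.24) for the carboxypeptidase-like gene scpl48 and 0.27 (SE 0.26) for AT1G65570. The reference genes had a median of -0.10 and an adjusted p of 0.965, with 0.36 (SE 0.23) for AT4G34270 and -0.18 (SE 0.22) for PEX4. Single list members differed by 0.73 (SE 0.37) for PRL, -0.37 (SE 0.25) for SIM, 0.34 (SE 0.24) for GI, 0.43 (SE 0.29) for RCA, 0.04 (SE 0.22) for STZ, -0.36 (SE 0.35) for UGT76C2 and -0.17 (SE 0.26) for GSO1. ARR15 and AT5G18600 exceeded background on 1 array at 4 h, EXPA18 on 1 untreated array, and RR16, RR18, UGT76C1, YUC4, EXPA7, AGL42, AT4G15690 and AT1G62500 on no array of either group.

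The contrast of 4 h against 1 h showed which signals moved between the early and the late sample, and it gave 5 calls. The unnamed 252123_at, 248625_at and 250533_at rose by 3.45 (SE 0.24), 3.57 (SE 0.27) and 3.14 (SE 0.26) on the log2 scale, with adjusted p of 0.0378, 0.0386 and 0.0487. YLS5 fell by 2.86 (SE 0.22, adjusted p = 0.0386) and 253534_at by 5.09 (SE 0.26, adjusted p = 0.0133). CHIL, a chalcone isomerase-like protein of flavonoid synthesis, came closest among the named genes that did not pass: it measured 6.88 untreated, 5.35 ± 0.62 at 1 h and 9.29 ± 0.01 at 4 h, a difference of 3.95 (SE 0.36, adjusted p = 0.0612). On 1 h replicate 2 CHIL lay below background, and with a pseudocount of 64 the difference was 2.91. The expansin EXPA4 measured 6.62 ± 0.45 at 1 h and 8.07 ± 0.03 at 4 h, a difference of 1.45 (SE 0.30, adjusted p = 0.311, and 0.00942 adjusted over the list alone).

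**Figure D3:**
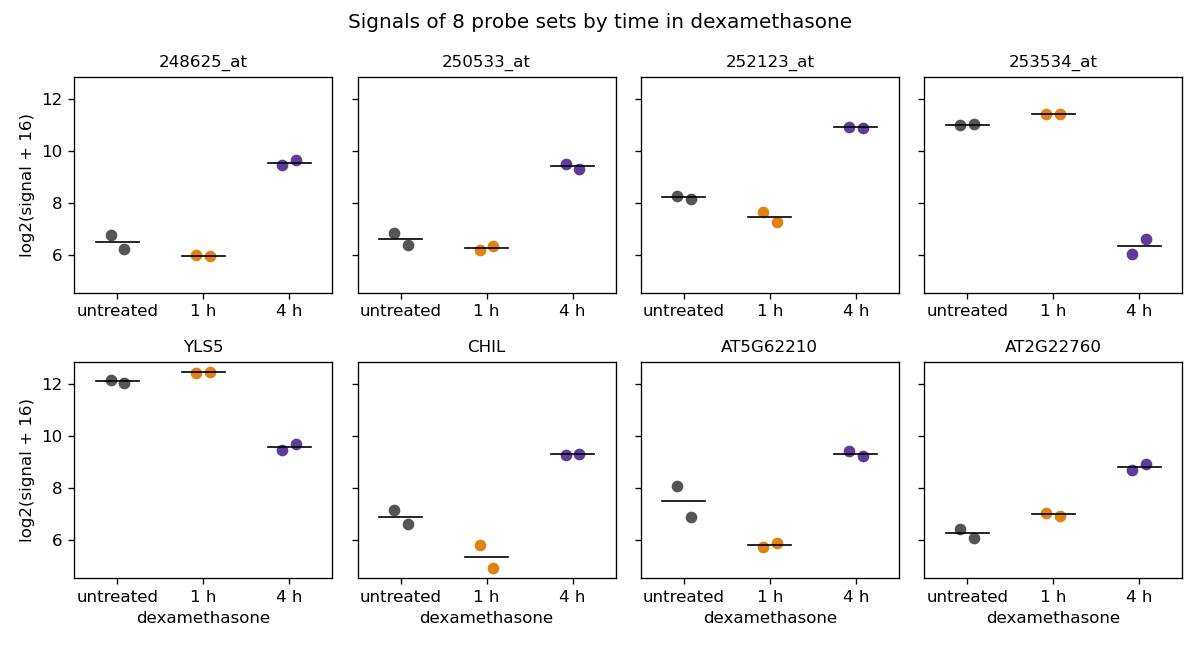
Log2 signal (y axis) of 8 probe sets in untreated cells and after 1 h and 4 h of dexamethasone (x axis); points are single arrays and lines group means. The first 5 panels hold the probe sets that passed between 4 h and 1 h, and in each of these both 4 h arrays lie at least 2.36 from the nearest other array.

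In all, 5 probe sets passed in limma, 3 higher and 2 lower at 4 h; 2101 had an unadjusted p under 0.05, of which 1064 were higher and 1037 lower. Leaving out any 1 array left 0, although the differences stayed close, at -2.97 to -2.75 for YLS5 and -5.39 to -4.79 for 253534_at, and the prior variance that follows the signal level gave 53. Beyond CHIL, the named genes with the smallest p were AT5G62210 (3.53, SE 0.40, adjusted p = 0.118), AT2G22760 (1.82, SE 0.24, adjusted p = 0.202), AT5G01210 (-2.05, SE 0.21, adjusted p = 0.101) and AT5G40450 (-1.94, SE 0.23, adjusted p = 0.130). AT5G62210 lay below background on 1 h replicate 2, and with a pseudocount of 64 its difference was 2.73. AT2G39280 and AT4G38660, below background at 1 h, were at least 1.72-fold and 1.48-fold higher at 4 h. AT1G15640 and AT3G05620, below background at 4 h, were at least 2.23-fold and 1.33-fold higher at 1 h.

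All 4 root cap markers were lower at 4 h than at 1 h, with a median log2 difference of -0.53, and the list's adjusted p in camera was 0.101. AT1G65570 differed by -0.88 (SE 0.26) and scpl48 by -0.85 (SE 0.24), and both passed when adjusted over the list alone (limma adjusted p = 0.0242). The auxin conjugation and inactivation genes had a median of 0.16 (adjusted p = 0.511), with 0.83 (SE 0.23) for GH3.17, 0.96 (SE 0.29) for the auxin oxidase gene AT1G14130, -0.22 (SE 0.24) for GH3.5 (WES1) and both groups below background for AT1G14120. Cell wall loosening had a median of 0.21 (adjusted p = 0.204), with 0.23 (SE 0.26) for XTH18. The adjusted p was 0.574 for auxin biosynthesis, 0.871 for Aux/IAA genes and 0.996 for reference genes (median -0.03). IAA30 differed by -0.89 (SE 0.36), PRL by 0.76 (SE 0.37), SIM by -0.29 (SE 0.25), GI by 0.16 (SE 0.24), RCA by 0.51 (SE 0.29), STZ by -0.11 (SE 0.22), YUC2 by -0.15 (SE 0.39), UGT76C2 by -0.01 (SE 0.35), AT4G34270 by 0.15 (SE 0.23) and PEX4 by -0.11 (SE 0.22). For RR16, above background on 1 array at 1 h, the bound was 1.09-fold in favour of 1 h (limma adjusted p = 0.632).

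Whether changes at 1 h persisted could not be settled from single genes: 0 probe sets passed at 1 h, so 0 could pass at both times. At an unadjusted p under 0.05 in both, 223 probe sets were higher and 119 lower at both times and 25 went in opposite directions. Independent lists would share 33.0 higher and 26.8 lower. Simulated groups without any effect, compared with simulated untreated arrays common to both contrasts, shared 363 in the same direction on average over 100 simulations. The observed number was 342. The log2 differences at 1 h and 4 h correlated across probe sets, which are not independent replicates, with r = 0.409, against 0.553 in the simulations. Their covariance was 0.0717 against a simulated 0.0843, a difference of -0.0126 that lay within the simulated range (0.0571 to 0.0935 for the covariance). With 1 untreated array used for each time, the covariance was -0.0227 or -0.00257. No overlap was thus seen beyond what shared untreated arrays gave in these simulations. They drew probe sets and arrays independently of each other, so deviations common to several real arrays or probe sets are not covered.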

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

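The contrast of 4 h against 1 h and the settings named here were planned; the gaps between arrays, and the use of those settings to weigh explanations, were chosen after the results were seen. The effect at 4 h differed from the effect at 1 h, by limma's test of the difference, for 5 probe sets. On the log2 scale the 4 h effect minus the 1 h effect was 3.57 for 248625_at, 3.14 for 250533_at, 3.45 for 252123_at, -5.09 for 253534_at and -2.86 for YLS5.

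In each of the 5 the 4 h arrays lay on one side of the other 4 arrays, with a smallest gap of 2.36, but probe sets picked for this contrast cannot test for a deviating array. All 5 were called with the columns as deposited, so they do not rest on the quantile normalization. Those columns had already been scaled to a common level, so the scaling before deposit was not tested. With a pseudocount of 64 all 5 were called as well, 253534_at at -4.43 (SE 0.17) and YLS5 at -2.79 (SE 0.15). The rises were smaller there, at 2.84 for 248625_at, 2.53 for 250533_at and 3.13 for 252123_at. That setting raised the count of calls from 5 to 42. Keeping these 5 thus cannot decide whether unstable logarithms of low signals play a part. With a pseudocount of 1 none was called (smallest adjusted p in limma 0.187), with differences of -5.40 (SE 0.32) for 253534_at and -2.89 (SE 0.22) for YLS5. A call at the threshold thus depends on the pseudocount. The differences kept direction and stayed beyond their spread, but probe sets picked by this same contrast could hardly do otherwise. What stays open is the source of the change. Dexamethasone itself, the hours between the samples and the induced ARR1 protein may each be involved, and the design has no array without the construct to separate them.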

How the results depend on the processing

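The background filter and the array weights were chosen after seeing the data. The count at 1 h was 0 under every alternative run. For 4 h against untreated (1 in the reported fit) and 4 h against 1 h (5), the counts were 29 and 26 without the lowest 40% of probe sets, 123 and 53 with a prior variance that follows the level, 108 and 42 with a pseudocount of 64, 0 and 0 with a pseudocount of 1, 0 and 0 with only the 4 arrays compared, 0 and 0 at an adjusted p under 0.01, 7 and 9 under 0.10, 0 and 0 over genes with a name instead of probe sets, and 8 and 17 with the background filter. The level-dependent prior split the 123 into 88 higher and 35 lower, and it shared 28 calls with the filter on the lowest 40%. Array weights gave 8 for 4 h against 1 h. The larger counts come with fewer dim probe sets or less weight on their spread; beyond that the cause was not tested. With each array left out in turn, which leaves a lone array assumed to vary like the other groups, both counts were 0 throughout. Of the 3 correlations of deviations between samples with the same number, 1 was above 0.1 (0.117, -0.02 and -0.04). These values do not bear out a pairing by number, but they cannot exclude one, and the labels do not say. With the replicate block the counts were 0 for 4 h against untreated and 5 for 4 h against 1 h, 2 of them shared with the reported fit. The covariance of the 1 h and 4 h changes (0.0717) was 0.244 with a pseudocount of 1, 0.0256 with a pseudocount of 64, and 0.0609 to 0.191 with an array left out. The number of list tests that passed (1 of 21) was 3 without the lowest 40%, 3 with the level-dependent prior, 3 with a pseudocount of 64, 0 with an estimated inter-gene correlation, and 0 to 2 with an array left out. The list gained was the root cap markers, in 2 contrasts. With the level-dependent prior they were higher at 1 h (camera adjusted p = 0.0290) and lower at 4 h than at 1 h (0.0182). Both contrasts use the same 1 h arrays, so these are not independent results. In the reported fit with an estimated correlation both tests had a camera adjusted p of 0.607. No called value changed sign. Of the values of named genes under settings other than leaving out an array, 1182 kept direction and side of the threshold, 48 newly passed, 3 ceased to pass and 15 changed sign without ever passing; with an array left out the numbers were 686, 0, 6 and 40. The robust prior was not run for lists, since camera has no such option. Signal over background limits what can be said of the named genes with the smallest p at 1 h, most of which lay close to it; without dim probe sets the count at 1 h was 0 as well.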

Other observations

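The tests in this part were chosen after the results were seen, except the fit with a prior variance that follows the signal level, which was planned. That fit called 123 probe sets for 4 h against untreated, 60 of them with a gene name, and the genes here are those with a symbol and a few loci without one that the report does not describe, picked after their values were seen. Among those that rose at 4 h was HEMA2, which starts tetrapyrrole synthesis, by 1.19 on the log2 scale (adjusted p = 0.0335); hemb2, named for a later step of that pathway, rose by 1.64 (adjusted p = 0.0474). CHIL rose by 2.41 (adjusted p = 0.0256), the dehydrin COR47 by 1.16 (adjusted p = 0.0367), the calmodulin-like CML38 by 1.34 (adjusted p = 0.0307) and the expansin-like EXLA2 by 1.12 (adjusted p = 0.0329). Of the loci without a symbol, AT1G71140 rose by 2.40, AT3G55720 by 2.31 and AT5G64230 by 2.14.

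In the same fit other named genes fell at 4 h. HAT2, a homeodomain-leucine zipper gene known to respond to auxin, fell by 1.33 (adjusted p = 0.0209) and WRKY22, a regulator of defence genes, by 1.37 (adjusted p = 0.0441). UGT74B1, a glucosyltransferase of glucosinolate synthesis, fell by 2.02 (adjusted p = 0.0337), the osmotin-like OSM34 by 1.33 (adjusted p = 0.0293) and cwINV6, of the cell wall invertase family, by 1.27 (adjusted p = 0.0249). YLS5 fell by 2.52 (adjusted p = 0.00131). Of the loci without a symbol, AT4G38540 fell by 2.40 and AT4G35200 by 1.88. The larger count came with that setting, and the reported fit called none of these genes against untreated.

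Of 30 symbol families and organelle genomes tested in 3 contrasts (90 tests), 3 passed, 2 of them of the plastid genome. Its 69 genes, assigned by symbol, had a median of -0.45 for 4 h against untreated (64 lower, camera adjusted p = 1.35e-06). For 4 h against 1 h the median was -0.57 (65 lower, camera adjusted p = 3.13e-11). Both calls were lost with an estimated correlation (adjusted p = 0.977). One untreated array may account for the first: without untreated replicate 2 it was -0.092, and without untreated replicate 1 it was -0.72. Whether 1 h replicate 2 sets the second stays open: without it the difference was -0.32, less than the gap between the untreated replicates, and without 1 h replicate 1 it was -0.88. Unequal labelling of RNA without poly(A) tails stays open. The plastid median followed the 25S ribosomal RNA control over the 6 arrays (Pearson r = 0.900, exact permutation p = 0.0278, adjusted 0.0556 over 2 relations; Spearman rho = 0.829, exact p = 0.0583, adjusted 0.103), with r = 0.741 without the 2 arrays farthest from the median. For 16 mitochondrial genes r was 0.777 (exact permutation p = 0.0569, adjusted 0.0569), rho was 0.771 (exact p = 0.103, adjusted 0.103), and r was 0.0954 without those 2 arrays. The permutations treated the 6 arrays as exchangeable, although they form 3 groups. A difference between groups in both values could therefore also give a small p.

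The third was the mitochondrial genome at 1 h, with 14 of 16 genes higher than untreated and a median of 0.44 (camera adjusted p = 0.0362, and adjusted p = 0.977 with an estimated correlation). Its medians per array were -0.02 and 0.57 at 1 h and -0.26 and 0.07 in untreated cells, so 1 h replicate 1 lay between the untreated arrays.

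Untreated replicate 1 stood apart on the second principal component. Degraded RNA is argued against by its GAPDH ratio of 3.11, the lowest of the 6 arrays. A dim hybridisation stays open: its 65.2% of probe sets above background lay inside the range of the others, but its median signal of 57.9 was the lowest of the 6. A part of organelle transcripts stays open: the SD of the untreated pair was 0.411 with them and 0.410 without, but 85 genes of 22746 probe sets are too few for this to decide. On the third component 1 h replicate 1 stood apart in the same way, with an SD of 0.407 for the 1 h pair; its 3' to 5' ratios for GAPDH (4.65) and ubiquitin (2.91) were the highest of the 6 arrays and that for actin (3.42) was not, so degraded RNA stays open there. No biological explanation was tested, since the labels give both untreated samples the same description.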
